A study of Homo sapiens with 45 samples.

How the data were processed

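The data are gene counts from RNA sequencing of 45 libraries, labelled T47D, a luminal, oestrogen receptor positive human breast cancer cell line. The libraries fall into 15 groups of 3 and were deposited as 4 tables, named here by their design: shRNA (9 libraries), hexanediol (9), rescue (15) and sgRNA (12). Per the labels' protocols, cells were grown in RPMI medium, infected with lentivirus and selected with hygromycin or puromycin, hypoxia was applied in a hypoxia workstation, and polyA RNA was sequenced as 150 bp read pairs. The oxygen level and the length of the hypoxia are not given in the sources used here, apart from the 24 h of hexanediol treatment. The labels do not say that replicates were separate cultures, so p-values measure the spread between libraries, which may be technical.

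The authors made the values as whole-number counts of reads per gene, not normalised; per the submitters' processing notes the tools were FastQC, HISAT2, featureCounts and DESeq2 with the hg38 genome, without versions. The roles, the annotation and the strand setting are not given in the sources used here. Counts of antisense and overlapping genes are therefore uncertain, as are those of genes that share sequence with a copy, such as ribosomal protein pseudogenes, HIST2H2AA4, SCDP1 and mitochondrial tRNA genes. Each table listed 60624 genes by Ensembl identifier, of which 60370 had a symbol in the reference gene-name table. Gene types, positions, GC content and length were taken from GENCODE release 29 on GRCh38, the build that hg38 names.

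Total counts per library were 17476890 to 19480495 in the shRNA table, 14111216 to 17713327 in the hexanediol table, 18056398 to 24760885 in the rescue table and 21225854 to 27217814 in the sgRNA table. The 45 pairs of replicates differed by more than counting noise, with a chi-square per degree of freedom of 1.77 to 29.7, so no library was counted as a duplicate. Counting intervals cover counting error only.

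Counts were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr, libraries were scaled by TMM, and 1 quasi-likelihood model was fitted per table to all of its groups, with robust dispersions (estimateDisp, glmQLFit, glmQLFTest). This left 14903 genes in the shRNA table, 16840 in the hexanediol table, 14302 in the rescue table and 15781 in the sgRNA table, with common biological coefficients of variation of 4.15%, 10.2%, 3.16% and 2.81%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and calls with an absolute log2 fold change of at least 1 (2-fold) are given as well. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. Levels are CPM values (edgeR's cpm function) computed from the deposited counts with TMM-scaled library sizes within each table; the tables were not normalised together, so levels set across tables are descriptive. Values are mean ± SD over n = 3 libraries unless stated.

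The 14 comparisons, the tests, the alternatives and 16 gene lists were fixed before the data were examined. The lists were glycolysis, hypoxia response, oestrogen response, cell cycle, EMT and matrix, integrated stress and unfolded protein response, heat shock response, cholesterol synthesis, oxidative phosphorylation, interferon response, NF-kB targets, p53 targets, immediate early genes, luminal epithelial markers, markers of basal, fibroblast and leukocyte cells, and ZHX2 with oxygen sensing factors. Each list was tested against the other genes with camera (limma 3.58.1) with an estimated correlation between genes, adjusted over the lists of a comparison; a preset correlation of 0.01 and fry were alternatives. Fry tests whether the genes of a list move one way on balance, against no change and not against the other genes. The set of genes higher in hypoxia and lower with shZHX2 in hypoxia was called the ZHX2-dependent hypoxia list and tested in the 12 comparisons of the other tables, adjusted over those 12. It was chosen on the libraries of the shRNA table.

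Genes were named by a fixed rule: ZHX2; per comparison the 8 largest rises and 8 largest falls (4 and 4 for 1% against 0.5% hexanediol, PA or SA against WT, and the difference of the sgZHX2 effects) among called genes with an average log2 CPM of at least 1, a proper symbol and groups that did not overlap; up to 3 members per list; and 10 members of the ZHX2-dependent list followed through all tables. Not all of these genes are given. Where a group held 1 to 3 counts of a gene, the ratio of summed counts is given with an exact 95% binomial interval.

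Replicate numbers were checked for pairing by correlating each library's deviations from its group mean. Of 22 pairs of groups within tables, only 0.5% and 1% hexanediol had every same-number correlation over 0.1 (0.12, 0.318 and 0.116), although 2 of the 6 libraries correlated best with their own number. The numbers were taken to pair those libraries, but the highest correlation between different numbers there was 0.168, so the pairing is uncertain. The main fits and the set tests did not use it, and the replicate block was an alternative. Shared control libraries were handled by 20 simulations of unchanged groups per pair of comparisons and by the overlap expected for independent lists.

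The tests were tried on simulated counts drawn from each comparison's own means and library sizes, with 200 changed genes. For hypoxia, where the simulation ran on 13924 genes, 91.7% of the 2-fold and 100% of the 4-fold changes were recovered, and 12 of 13736 unchanged genes were called. For 0.5% hexanediol, with 16170 genes, 68.8% of the 2-fold and 95.4% of the 4-fold changes were recovered and 7 of 15977 unchanged genes were called. All genes beyond the 200 were left unchanged, whereas 79.9% of the genes tested were called in the real hypoxia comparison. The simulations therefore do not cover scaling when most genes change.

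Settings tried beside these, and fixed with them, were median-of-ratios scaling (RLE), no low-count filter, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, each library left out, the set test options above, correlations over genes with an average log2 CPM of at least 3, and a 2-fold limit for the ZHX2-dependent list. Added after the data were seen were scaling by library size only, a GC and length correction (loess, span 0.3), leaving out both second hexanediol libraries, leaving out 106 genes abundant in the shRNA and hexanediol tables and near 0 in the rescue table, and the set test of the 2-fold members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.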

Results

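Gene expression was measured by RNA sequencing in 45 libraries labelled T47D, with 3 libraries in each of 15 groups. ZHX2 is a zinc finger and homeobox transcription factor. The shRNA table held cells with a control hairpin (shCtrl) in normoxia and in hypoxia and cells with a hairpin against ZHX2 (shZHX2) in hypoxia. The hexanediol table held hypoxic cells treated for 24 h with 0.5% or 1% 1,6-hexanediol, an alcohol used to disturb phase-separated condensates, and hypoxic control cells. The rescue table held hypoxic shCtrl cells with vector and shZHX2 cells with vector or with ZHX2 forms labelled WT, PA or SA. The sgRNA table held hypoxic cells labelled sgCtrl, sgZHX2, teton_control and teton_sgZHX2. The stated aims were to find genes that are induced by hypoxia and positively regulated by ZHX2, and to measure expression after phase separation was disturbed. Total counts per library ranged from 14111216 to 27217814.

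The ZHX2 transcript (ENSG00000178764, chromosome 8, 122781394 to 122974512, plus strand, on GRCh38) was lower in shZHX2 cells without a rescue form than in their controls. In the shRNA table it stood at 5.15 ± 1.53 CPM with shZHX2 and 18.8 ± 2.64 CPM with shCtrl in hypoxia (log2 fold change -1.86, SE 0.15, adjusted p = 3.6e-10), and at 16.9 ± 1.24 CPM in normoxia. Hypoxia against normoxia gave no call for ZHX2 (log2 fold change 0.15, SE 0.12, adjusted p = 0.265). In the rescue table it fell from 32.0 ± 1.99 CPM in shCtrl cells to 6.86 ± 0.545 CPM in shZHX2 cells with vector (log2 fold change -2.22, SE 0.07). It reached 72.3 ± 1.44 CPM with WT, 54.0 ± 0.436 CPM with PA and 80.5 ± 2.26 CPM with SA, all above the shCtrl level. With sgRNAs the level was 45.1 ± 1.36 CPM in sgCtrl, 49.6 ± 1.69 CPM in sgZHX2, 47.5 ± 1.85 CPM in teton_control and 49.3 ± 1.34 CPM in teton_sgZHX2; it was called slightly higher with sgZHX2 (log2 fold change 0.13, SE 0.04, adjusted p = 0.0044; -0.03 and no call after a GC and length correction added once the data were seen) and not called with teton_sgZHX2 (0.05, SE 0.04, adjusted p = 0.242). A transcript level does not show whether a guide edited the gene. ZHX2 was also higher with 0.5% hexanediol, at 18.3 ± 2.24 CPM against 12.01 CPM in its control (log2 fold change 0.60, SE 0.12, adjusted p = 0.000956).

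**Figure D1:**
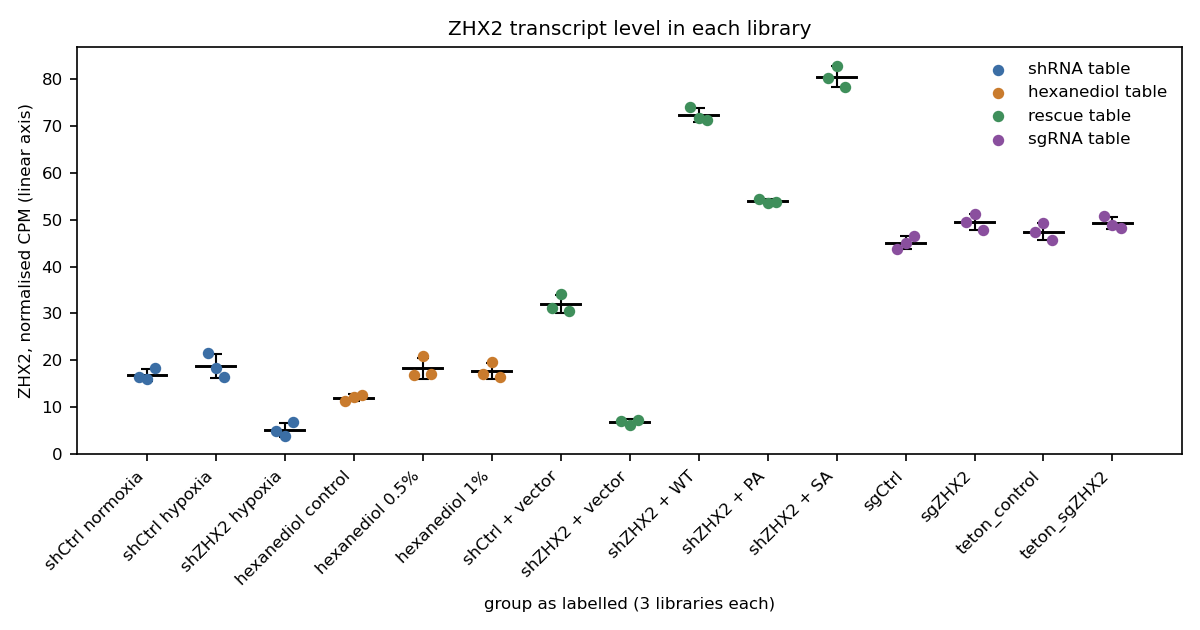
ZHX2 transcript level (vertical axis, normalised CPM, linear) in each library (points) of the 15 groups (horizontal axis), coloured by table; lines are means and bars SD, n = 3, and the tables were not normalised together. The shZHX2 groups without a rescue form sit at 5.15 and 6.86 CPM, below their controls at 18.8 and 32.0 CPM, while the 4 sgRNA groups lie between 45.1 and 49.6 CPM.

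Hypoxia in shCtrl cells raised 19 of 20 glycolysis genes (adjusted p = 0.000917 with an estimated correlation) and 26 of 28 hypoxia response genes (adjusted p = 0.00026) and lowered 23 of 28 cell cycle genes (adjusted p = 0.0125). CA9, a carbonic anhydrase that is a widely used hypoxia marker (chromosome 9, 35673856 to 35681159), rose from 1 count summed over the normoxic libraries to 1119 counts, a ratio of 1583 with a counting interval of 283.5 to 62570. PTPRN, a protein of secretory granule membranes, rose from 2 to 500 counts (ratio 353.6, counting interval 97.4 to 2928). NDRG1, a stress-responsive gene, rose 72.0-fold to 485 ± 7.44 CPM against 6.71 ± 0.780 CPM (log2 fold change 6.17, SE 0.04). Other large rises were PPP1R3C, which targets a phosphatase to glycogen (49.6-fold), KISS1R, the kisspeptin receptor (40.1-fold), PPFIA4 (37.3-fold), SCNN1G, a subunit of the epithelial sodium channel (36.6-fold), and ISM2 (33.6-fold). The largest falls were 19.3-fold for ATR, a DNA damage checkpoint kinase (from 23.2 ± 1.27 CPM), 18.9-fold for CEP295, 18.8-fold for the chaperone gene HSPH1 (3.36 ± 0.486 CPM against 63.3 ± 0.985 CPM), 18.5-fold for AKAP9, 18.2-fold for the kinesin gene KIF15, 17.9-fold for CENPF of the kinetochore, and 17.8-fold for GOLGA4 of the Golgi. Of 14903 genes tested, 6421 were higher and 5485 lower in hypoxia, and 2286 and 3243 of these changed at least 2-fold. After the GC and length correction 3451 of the higher and 3334 of the lower genes kept their call.

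Among the fixed lists, 19 of 20 glycolysis genes rose and 0 fell (median log2 fold change 2.05, adjusted p = 0.000917 with an estimated correlation). The list held SLC16A3, the lactate exporter (19.3-fold), and PFKFB4, a regulator of glycolytic flux (15.5-fold). Of 28 hypoxia response genes, 26 rose and 1 fell (median 2.11, adjusted p = 0.00026 with an estimated correlation); the 1 that fell was PLOD2, a collagen lysyl hydroxylase (-0.90, SE 0.05; 0.57 after the GC and length correction). Of 28 cell cycle genes, 23 fell and 4 rose (adjusted p = 0.0125), with TOP2A, the mitotic topoisomerase, at -3.74, MCM6 of the replicative helicase at -3.22, and BIRC5 higher by 0.34 on the log2 scale (-0.14 with scaling by library size only). Of 15 heat shock genes, 9 fell and 3 rose (adjusted p = 0.00397), including HSP90AA1 at -3.53. Luminal epithelial markers rose in 13 of 14 cases (adjusted p = 0.044), including the keratins KRT8 (1.46) and KRT19 (1.46), while AGR2 fell (-0.49; 0.02 and no call after the GC and length correction). Cholesterol synthesis genes rose in 13 and fell in 5 of 19 cases (adjusted p = 0.0275), with INSIG1 at 1.99; their median of 0.38 is smaller than the shift of all genes under scaling by library size only, so its sign depends on the scaling. The counts adjusted over the list alone were the same in these lists.

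The other lists gave no call with an estimated correlation. EMT and matrix genes were higher in 11 and lower in 1 of 17 cases (adjusted p = 0.0594), with TGFBI at 2.91, and immediate early genes in 9 and 1 of 13 (adjusted p = 0.0503), with FOS at 3.11. NF-kB targets gave 10 higher and 2 lower of 13 (adjusted p = 0.103), with ICAM1 at 2.22, and oestrogen response genes 14 and 8 of 22 (adjusted p = 0.377), with MYC at 1.46 and NRIP1 at -3.13. Stress response genes gave 12 and 7 of 19 (adjusted p = 0.845) and interferon genes 5 and 8 of 18 (adjusted p = 0.774). In 4 lists the median and the mean differed in sign: oxidative phosphorylation (12 higher, 9 lower of 24; median 0.13, mean -0.13, adjusted p = 0.779), p53 targets (9 and 7 of 16; 0.26 and -0.17, adjusted p = 0.772), ZHX2 and oxygen sensing factors (5 and 5 of 13; 0.08 and -0.34, adjusted p = 0.569) and the basal, fibroblast and leukocyte markers (2 and 1 of 5; 0.24 and -0.02, adjusted p = 0.845). Adjusted over the list alone, 13 oxidative phosphorylation genes were higher and 0 immediate early genes lower, and the other counts were the same. HIF1A itself fell (-3.84, SE 0.08). Fold changes followed GC content across genes (Spearman rho 0.694), and the mitochondrial share of counts was 4.55% to 4.76% in normoxia and 9.12% to 9.57% in hypoxia. With scaling by library size only, the median of all genes moved by -0.49 on the log2 scale and the calls became 3385 higher and 8061 lower, 29.6% higher against 53.9%; a shift of that size exceeds the medians of the oestrogen, stress, interferon, cholesterol, p53, oxidative phosphorylation, basal and ZHX2 lists.

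With shZHX2 in hypoxia, where ZHX2 fell by 1.86 on the log2 scale, 17 of 19 cholesterol synthesis genes (adjusted p = 0.00378 with an estimated correlation) and 26 of 28 cell cycle genes (adjusted p = 0.0326) fell. Among single genes, CTNND2, a catenin of the adherens junction, rose 15.7-fold (5.71 ± 0.925 CPM against 0.357 ± 0.0378 CPM), C12orf76 14.3-fold (54.8 ± 1.37 CPM against 3.81 ± 0.539 CPM), LINGO4 12.9-fold, MAN1A1, a mannosidase of glycan processing, 7.80-fold, and CYP1A1, a target of the aryl hydrocarbon receptor, 7.23-fold (118 ± 2.43 CPM against 16.3 ± 1.36 CPM). ACTL8 fell 27.9-fold (0.372 ± 0.0373 CPM against 10.5 ± 0.724 CPM), NIPAL4 15.7-fold, IVL, the cornified envelope protein involucrin, 15.5-fold, PLLP 11.3-fold, the actin crosslinker FLNC 10.8-fold and DUSP6, a phosphatase of ERK, 9.58-fold. Across all genes 5006 were higher and 4955 lower, 1372 and 1436 of them at least 2-fold.

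Cholesterol synthesis genes fell in 17 and rose in 0 of 19 cases (adjusted p = 0.00378 with an estimated correlation), with INSIG1 at -1.65 (SE 0.05). Cell cycle genes fell in 26 and rose in 0 of 28 cases (adjusted p = 0.0326), with MCM5 and BIRC5 both at -1.05. Hypoxia response genes did not move one way: 12 were higher and 7 lower of 28 (adjusted p = 0.67), with STC2 at -1.96, CA12 at -1.28 and the oxygen sensor gene EGLN3 at 0.95. Their median was 0.08, their mean -0.05 and their test downward. Glycolysis gave 6 higher and 14 lower of 20 (adjusted p = 0.303), with HK2 at 1.39 and PFKL at -0.99. Oestrogen response gave 8 higher and 11 lower of 22 (adjusted p = 0.993; median -0.12, mean 0.11, test upward), with TFF1 at 2.43 and MYC at -1.06. No call with an estimated correlation was found for luminal markers (2 higher, 11 lower, adjusted p = 0.0888; KRT8 -1.43), p53 targets (10 and 3, adjusted p = 0.1; RRM2B 1.51), EMT and matrix (4 and 9, adjusted p = 0.132; L1CAM -2.37) or NF-kB targets (3 and 8, adjusted p = 0.216). In the last list ICAM1 was at -2.77, and CCL2 fell from 36 to 2 counts, a ratio of 20.4 with a counting interval of 5.24 to 174.4. The counts adjusted over the list alone were the same in all of these lists. The mitochondrial share was 11.9% to 12.4% with shZHX2. With scaling by library size only, the median of all genes moved by 0.23, more than the medians of the hypoxia and oestrogen response lists, and 67.6% of the calls were higher against 50.3%.

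The comparison that the series names as its aim, genes higher in hypoxia and lower with shZHX2 in hypoxia, gave 2916 genes against 2135 expected for independent lists (odds ratio 2.63, Fisher's exact p 3.06e-165 across genes, which are not independent replicates). At 2-fold in both comparisons there were 451 genes against 220.3 expected. The opposite class, lower in hypoxia and higher with shZHX2, held 2199 genes (1842 expected), while 1855 genes were higher in both (2157 expected) and 1323 lower in both (1824 expected). Both comparisons used the same shCtrl hypoxia libraries. Simulated unchanged groups gave an overlap of 0.1 genes, a correlation of -0.541 and a covariance of -0.0212. The observed correlation was -0.214 and the covariance -0.233. With no gene changed almost none is called, so the simulated overlap cannot show how shared controls act when most genes change. Part of the excess overlap may come from the shared controls. With scaling by library size only, 1199 genes met both conditions.

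The 10 members of this class followed through all tables were PTPRN, KISS1R, ISM2, CCN5, ANGPTL4, SPAG4, SLC16A3, DPYSL4, PRTN3 and ALDOC. With shZHX2, ISM2 fell most (-2.71, SE 0.23), followed by CCN5, a matricellular protein of the CCN family (-2.45, SE 0.13), PTPRN (-1.43, SE 0.16) and ANGPTL4, a secreted inhibitor of lipoprotein lipase (-1.19, SE 0.04). The other 6 fell by less than 2-fold, KISS1R with -0.99, DPYSL4 with -0.90, SLC16A3 with -0.78, PRTN3 with -0.73, SPAG4 with -0.42 and the glycolytic aldolase gene ALDOC with -0.22 on the log2 scale (0.01 and no call with scaling by library size only).

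**Figure D2:**
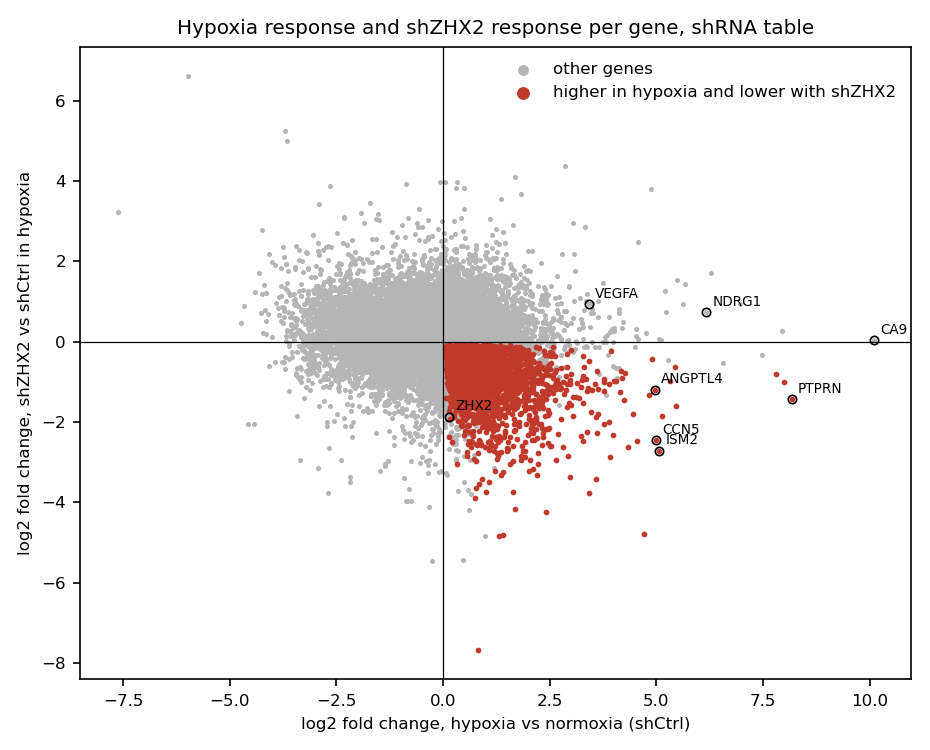
Log2 fold change of each gene (point) with shZHX2 in hypoxia (vertical axis) against that with hypoxia in shCtrl cells (horizontal axis), n = 3 libraries per group. The 2916 genes in red are higher in hypoxia and lower with shZHX2; ISM2 lies at 5.07 and -2.71, and a shared control group ties the axes together.

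With 0.5% hexanediol in hypoxia all 28 cell cycle genes fell (adjusted p = 0.00459 with an estimated correlation), and the largest rise was that of the testis chaperone CLGN (11.4-fold, 49.6 ± 8.48 CPM against 4.34 ± 0.658 CPM). The largest falls were FAM111B (19.4-fold, 8.74 ± 2.06 CPM against 170.4 ± 3.93 CPM), CLSPN of the replication checkpoint (17.4-fold), MCM10, a replication initiation factor (14.9-fold), DTL (12.5-fold), UHRF1, which maintains DNA methylation (12.4-fold), the imprinted RNA H19 (11.1-fold), and the origin factors CDC6 (11-fold) and CDC45 (10.5-fold). STEAP1 rose 6.84-fold, NCMAP 6.44-fold, the neurotrophin receptor NGFR 6.36-fold and FAM167A 4.65-fold. FIBIN rose from 2 to 24 counts (ratio 11.4, counting interval 2.82 to 99.2) and GNG2 from 2 to 15 (7.10, 1.65 to 64.0). Of 16840 genes, 3265 were higher and 3301 lower, 488 and 778 at least 2-fold.

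All 28 cell cycle genes fell (28 adjusted over the list alone; adjusted p = 0.00459 with an estimated correlation), RRM2, a subunit of ribonucleotide reductase, being at -3.38. Oestrogen response genes fell in 12 and rose in 1 of 22 cases (adjusted p = 0.0494), with the trefoil genes TFF1 at -1.47 and TFF3 at -1.43. Cholesterol synthesis gave 17 lower of 20 (adjusted p = 0.467), with MVD at -1.45, and oxidative phosphorylation 16 lower of 24 (adjusted p = 0.58). Interferon genes gave 10 higher and 1 lower of 18 (adjusted p = 0.58; OAS1 1.91) and stress response genes 9 and 3 of 20 (adjusted p = 0.526; CHAC1 2.35, DDIT3 1.94). The counts of these lists adjusted over the list alone were the same apart from 11 higher interferon genes. Glycolysis genes fell in 6 and rose in 0 of 20 cases (4 lower adjusted over the list alone, adjusted p = 0.58), with PGAM1 at -1.30 and ENO1 at -1.15. Hypoxia response genes gave 1 higher and 2 lower of 29 (1 and 1 adjusted over the list alone, adjusted p = 0.816). The second 0.5% library stood apart here: it was the lowest of its group in 45 of the 49 genes of these lists, as the second 1% library was of its own in 46. Without both second treated libraries, left out after the data were seen, glycolysis gave 1 higher and 18 lower at a median of -0.71 in place of -1.04, and hypoxia response 7 higher and 12 lower at a median of -0.15 in place of -0.48. Stress response gave 5 lower. Without the second 0.5% library alone glycolysis gave 6 lower and hypoxia response 1 higher and 5 lower.

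With 1% hexanediol 13 of 15 luminal markers (adjusted p = 0.0335 with an estimated correlation) and 16 of 22 oestrogen response genes (adjusted p = 0.0032) fell. NGFR rose 95.1-fold (169 ± 9.42 CPM against 1.76 ± 0.0418 CPM), CLGN 88.3-fold, LAMP3, a lysosomal membrane protein induced by stress, 87.5-fold (218 ± 24.7 CPM against 2.49 ± 0.202 CPM), and the stress cytokine GDF15 60.9-fold. FIBIN rose from 2 to 675 counts (ratio 293.7, counting interval 81.0 to 2430) and GNG2 from 2 to 509 (221.5, 61.0 to 1834). VTCN1, an immune checkpoint ligand, fell 38.1-fold (2.33 ± 0.802 CPM against 87.8 ± 3.41 CPM), IVL 32.5-fold, ANGPTL4 28.8-fold (3.62 ± 1.96 CPM against 103 ± 4.28 CPM), the cadherin CDH10 22.9-fold and UHRF1 21.4-fold. In all 5084 genes were higher and 5439 lower, 1875 and 2143 at least 2-fold.

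Oestrogen response genes fell in 16 and rose in 3 of 22 cases (adjusted p = 0.0032 with an estimated correlation), with TFF1 at -4.17 and PGR, the progesterone receptor, at -3.10. Luminal markers fell in 13 of 15 cases (adjusted p = 0.0335), with KRT19 at -3.80 and KRT8 at -3.15. Stress response genes were higher in 17 and lower in 1 of 20 (adjusted p = 0.0504), with DDIT3 at 4.76 and CHAC1 at 4.40, both targets of ATF4. Glycolysis genes fell in 15 of 20 cases (17 adjusted over the list alone, adjusted p = 0.608), with PFKFB3 at -3.27 and LDHA, lactate dehydrogenase, at -2.71. Hypoxia response gave 1 higher and 11 lower of 29 (1 and 10 adjusted over the list alone, adjusted p = 0.608), with CITED2 at -4.07 and NDUFA4L2 at 2.05. The second 1% library was the lowest of its group in 46 of the 49 genes of these lists. Without both second treated libraries these lists gave 1 higher and 19 lower, and 7 higher and 19 lower. Cell cycle genes gave 7 higher and 14 lower of 28 (adjusted p = 0.261; MCM5 -3.05). Without the second 1% library 4 of them were higher, and without both second treated libraries 10. Cholesterol synthesis gave 1 and 15 of 20 (adjusted p = 0.452; MVD -2.53), p53 targets 9 and 1 of 16 (adjusted p = 0.261) and interferon genes 11 and 2 of 18 (adjusted p = 0.549; IFIT1 2.85). Apart from glycolysis and hypoxia response, the counts adjusted over the list alone were the same. With scaling by library size only, the median of all genes moved by 0.12 at 0.5% and 0.18 at 1%, and 66.0% and 59.8% of the calls were higher against 49.7% and 48.3%.

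**Figure D3:**
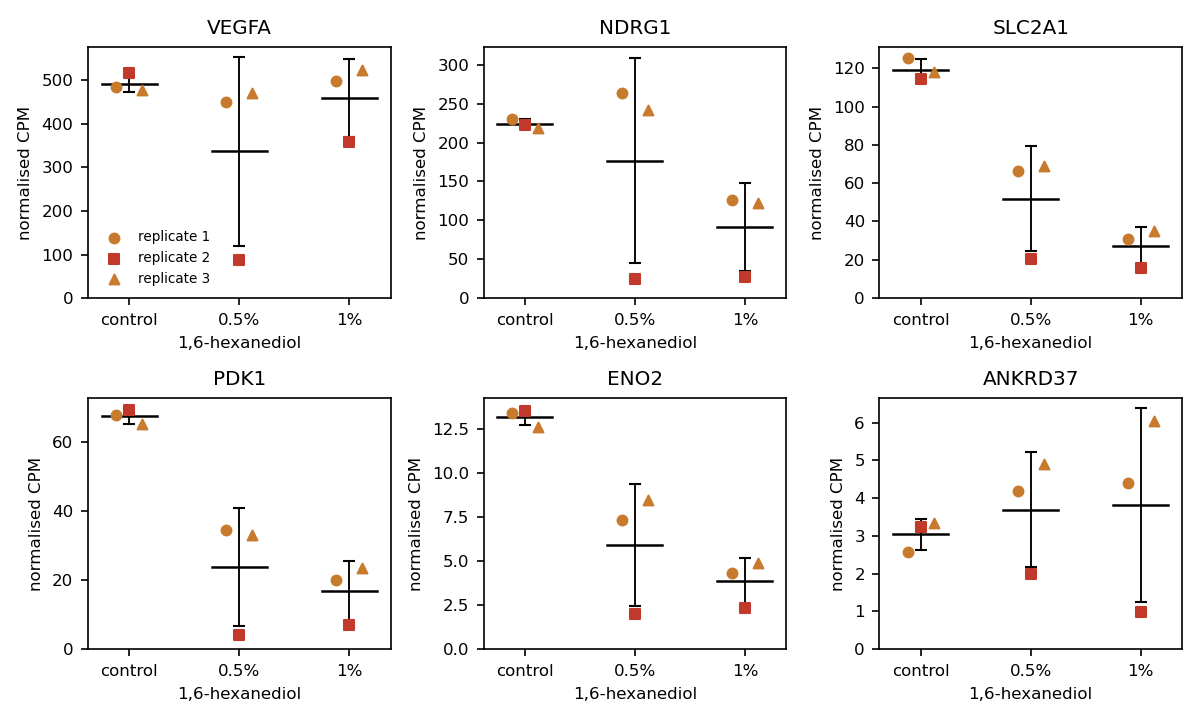
Normalised CPM (vertical axes, linear) of VEGFA, NDRG1, SLC2A1, PDK1, ENO2 and ANKRD37, chosen after their values were seen, in each library (points, shaped by replicate number) by 1,6-hexanediol dose (horizontal axes); lines are means and bars SD, n = 3. The second 0.5% library lies at 87.3 CPM for VEGFA against 451 and 472 in the other 0.5% libraries, and at 24.8 CPM for NDRG1 against 263.5 and 242; the second 1% library lies at 26.5 CPM for NDRG1 against 126 and 122.

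The doses were set against each other directly. At 1% against 0.5%, INHBE, an inhibin subunit gene, was 37.4-fold higher (15.1 ± 0.782 CPM against 0.395 ± 0.0607 CPM), KCNE4 31.1-fold, GNG2 30.7-fold and DIRAS3 30.4-fold. CCDC177 was 23.9-fold lower, SRARP 20.3-fold and CDH10 20.1-fold. Luminal markers were lower at 1% in 14 and higher in 1 of 15 cases (adjusted p = 0.0154 with an estimated correlation; 14 and 1 adjusted over the list alone) and oestrogen response genes in 15 and 3 of 22 (adjusted p = 0.00907; 15 and 3 adjusted over the list alone; PGR -3.09). Cell cycle genes were higher at 1% in 24 of 28 cases (25 adjusted over the list alone, adjusted p = 0.0665), with MKI67 at 1.77, and stress response genes in 18 of 20 (19 adjusted over the list alone, adjusted p = 0.0665), with DDIT3 at 2.82 and ATF3 at 2.75. Glycolysis gave 7 lower of 20 (adjusted p = 0.978), 16 lower without the second 0.5% library, 1 higher and 5 lower without the second 1% library, and 1 higher and 18 lower without both. In all 4762 genes were higher and 4673 lower at 1%. Both doses shared the control libraries: their fold changes correlated with 0.506 (simulated unchanged groups 0.517) and had a covariance of 0.302 (simulated 0.0278), and 2091 genes were higher at both doses (985.7 expected) and 2208 lower (1066 expected).

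In the rescue table, shZHX2 with vector against shCtrl with vector lowered 24 of 29 hypoxia response genes (adjusted p = 3.08e-05 with an estimated correlation) and 27 of 28 cell cycle genes (adjusted p = 2.93e-05) and raised 16 of 16 p53 targets (adjusted p = 2.93e-05), with ZHX2 at -2.22. DKK1, a secreted Wnt antagonist, fell 12.2-fold (1.24 ± 0.367 CPM against 15.5 ± 0.792 CPM), VTCN1 9.44-fold, LDLRAD4, an inhibitor of TGF-beta signalling, 7.12-fold, BCAS1 7.07-fold and the gap junction gene GJA1 6.85-fold. STMN4, a stathmin, rose 25.7-fold (9.58 ± 0.115 CPM against 0.367 ± 0.0646 CPM), CHAC1, a glutathione-degrading target of ATF4, 15.2-fold (23.4 ± 0.645 CPM against 1.53 ± 0.253 CPM), SEMA6A 14.2-fold, the interferon-induced RSAD2 10.9-fold and the inducible chaperone HSPA6 10.1-fold. CXCL2 rose from 2 to 47 counts (ratio 21.2, counting interval 5.54 to 179.9). In all 4849 genes were higher and 5045 lower, 1029 and 1030 at least 2-fold.

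Hypoxia response genes fell in 24 and rose in 4 of 29 cases (adjusted p = 3.08e-05 with an estimated correlation), with LOX, a collagen crosslinking oxidase, at -2.09, and glycolysis genes fell in 17 and rose in 2 of 21 (adjusted p = 0.00478), with the glucose transporter SLC2A3 at -2.71. Cell cycle genes fell in 27 and rose in 1 of 28 (adjusted p = 2.93e-05), with TOP2A at -1.88 and E2F1 at 0.69. All 16 p53 targets rose (adjusted p = 2.93e-05; GDF15 2.22), as did 18 of 21 interferon genes (adjusted p = 4.14e-05; IFI44L 1.80) and 17 of 20 stress response genes, while 3 fell (adjusted p = 4.4e-05; SDF2L1 1.76). EMT and matrix genes fell in 12 and rose in 5 of 18 cases (adjusted p = 0.00437), with THBS1 at -2.41 and MMP14 at 2.51. Luminal markers fell in 12 of 14 (adjusted p = 0.00209), oestrogen response genes in 15 of 22 (adjusted p = 0.00586; AREG -2.24), cholesterol synthesis genes in 17 of 20 (adjusted p = 0.014), and immediate early genes in 6 of 13 while 2 rose (adjusted p = 0.014; EGR1 -2.09). The counts adjusted over the list alone were the same in all of these lists. Oxidative phosphorylation genes were higher in 15 and lower in 4 of 24 (adjusted p = 0.0881), and heat shock genes had a median of -0.09 and a mean of 0.14 (adjusted p = 0.388).

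With WT ZHX2 added to shZHX2 cells, 24 of 29 hypoxia response genes rose (adjusted p = 2.11e-05 with an estimated correlation) and 15 of 16 p53 targets fell (adjusted p = 8.62e-05). DKK1 rose 15.6-fold (19.7 ± 0.361 CPM against 1.24 ± 0.367 CPM), LDLRAD4 8.42-fold, AFAP1L2 7.45-fold, the semaphorin SEMA3C 6.78-fold (511 ± 3.55 CPM against 75.5 ± 2.71 CPM) and the coagulation inhibitor TFPI 6.67-fold. CHAC1 fell 16.9-fold, KLHDC7B 14.7-fold, HSPA6 12.8-fold, STMN4 10.0-fold, RSAD2 9.99-fold and HOXB9 9.98-fold. The mitochondrial tRNA genes MT-TN and MT-TC fell 76.6-fold and 39.7-fold; the mitochondrial share of counts was 0.312% to 0.333% with WT and 0.785% to 0.807% with vector. Hypoxia response genes rose in 24 and fell in 5 of 29 (adjusted p = 2.11e-05 with an estimated correlation), and cell cycle genes rose in 24 and fell in 1 of 28 (adjusted p = 0.00123). P53 targets fell in 15 of 16 (adjusted p = 8.62e-05), stress response genes in 16 of 20 (adjusted p = 8.62e-05) and interferon genes in 14 of 21 (adjusted p = 0.00104). Heat shock genes rose in 11 and fell in 3 of 14 (adjusted p = 0.00366), with HSP90AA1 at 1.61. The counts adjusted over the list alone were the same in these lists. Of the 5045 genes lower with shZHX2, 3699 were higher with WT than with vector (1769 expected), and of the 4849 higher genes 3609 were lower with WT (1678 expected). The vector libraries were shared: the correlation was -0.782 (simulated -0.464), the covariance -0.447 (simulated -0.0167) and the simulated overlaps 0 and 0.05, and part of the excess may come from the shared controls. The simulated groups were unchanged, so their overlaps cannot show how shared controls act when most genes change.

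With PA and SA the ZHX2 transcript was 7.85-fold and 11.7-fold above vector. With PA 3536 genes were higher and 3270 lower, 65 and 71 at least 2-fold; with SA 2892 and 3072, 62 and 32 at least 2-fold; with WT 1018 and 1129 changed at least 2-fold. Apart from ZHX2, the larger changes with PA were FGB, a fibrinogen chain (2.28-fold higher), the sodium channel gene SCNN1G (1.90-fold higher, 25.6 ± 1.43 CPM against 13.5 ± 0.942 CPM), RBBP8 of DNA end resection (1.83-fold higher) and COPS9 of the signalosome (2.03-fold lower, 11.6 ± 0.495 CPM against 23.5 ± 0.905 CPM), besides pseudogenes whose counts are uncertain. With SA, RGS22 (2.31-fold), FGB (2.11-fold) and the cold-inducible RBM3 (2.02-fold, 512 ± 21.7 CPM against 254 ± 0.846 CPM) were higher and CBS, of cysteine synthesis, was lower (2.06-fold, 27.9 ± 7.07 CPM against 57.7 ± 18.5 CPM). Hypoxia response genes were higher in 16 and lower in 5 of 29 cases with PA (adjusted p = 0.00719 with an estimated correlation; 6 lower adjusted over the list alone) and in 16 and 5 with SA (adjusted p = 0.00681), none by 2-fold; ERO1A was at 0.50 and 0.52. Oxidative phosphorylation genes fell in 18 of 24 with PA (adjusted p = 0.00719; COX5B -0.80), and cholesterol synthesis genes rose in 12 and fell in 6 of 20 with SA (adjusted p = 0.0252; IDI1 0.71); the other counts given here were the same adjusted over the list alone. Fold changes against vector followed GC content across genes (Spearman rho -0.482 with PA and -0.541 with SA). The mitochondrial share of counts was 1.16% to 1.26% with PA and 1.12% to 1.19% with SA, against 0.785% to 0.807% with vector. PA and SA shared the vector libraries: 1787 genes were higher with both (715 expected) and 1859 lower (702.4 expected), with a correlation of 0.572 (simulated 0.501) and a covariance of 0.0691 (simulated 0.0169), and part of the excess may come from the shared controls. With scaling by library size only, the median of all genes for PA against vector moved by 0.15 and the calls became 5804 higher and 1794 lower, 76.4% higher against 52.0%. After the GC and length correction 2157 genes were higher with PA, and 1894 higher and 1894 lower with SA.

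PA and SA were set against WT directly. DKK1 was 9.60-fold lower with PA (from 19.7 ± 0.361 CPM) and 11.7-fold lower with SA, LDLRAD4 10.9-fold and 7.11-fold lower, and HSPA6 11.3-fold and 10.1-fold higher. CHAC1 was higher by 3.42 and 3.29 on the log2 scale. Hypoxia response genes were lower in 22 and higher in 6 of 29 cases with PA and in 21 and 4 with SA (adjusted p = 2.91e-05 and 1.69e-05 with an estimated correlation), with LOX at -1.83 and -1.80. Cell cycle genes were lower in 25 and 23 of 28 (adjusted p = 0.000398 and 0.00036), with CCNB1 at -1.25 and -1.13. P53 targets were higher in 15 and 16 of 16 (adjusted p = 7.9e-05 and 5.85e-05), stress response genes in 17 and 17 of 20 (adjusted p = 7.9e-05 and 3.92e-05) and interferon genes in 16 and 15 of 21 (adjusted p = 0.000622 and 0.00069). Adjusted over the list alone, SA gave 24 lower cell cycle genes and 16 higher interferon genes, and the other counts were the same. In all 4742 genes were higher and 4826 lower with PA than with WT, and 4590 and 4574 with SA. MT-TN and MT-TC were 60.6-fold and 39.3-fold higher with PA, where the mitochondrial share was 1.16% to 1.26%.

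Without shared libraries, the fold changes of shZHX2 with vector correlated across genes with those of PA against WT (0.634) and SA against WT (0.712); genes are not independent replicates. Of the 3699 genes lower with shZHX2 and higher with WT, 1812 were also higher with PA than with vector and 1524 with SA, and 2913 were lower with PA than with WT and 3114 with SA; these counts share vector or WT libraries with the choice of the genes. Their median log2 fold change against vector was 0.66 with WT, 0.22 with PA and 0.16 with SA. The transcript level of PA was 2.97 and that of SA 3.55 above vector on the log2 scale, against 3.40 for WT. For PA against WT, scaling by library size only moved the median of all genes by 0.25 and gave 7012 higher and 2913 lower genes, 70.7% higher against 49.6%.

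**Figure D4:**
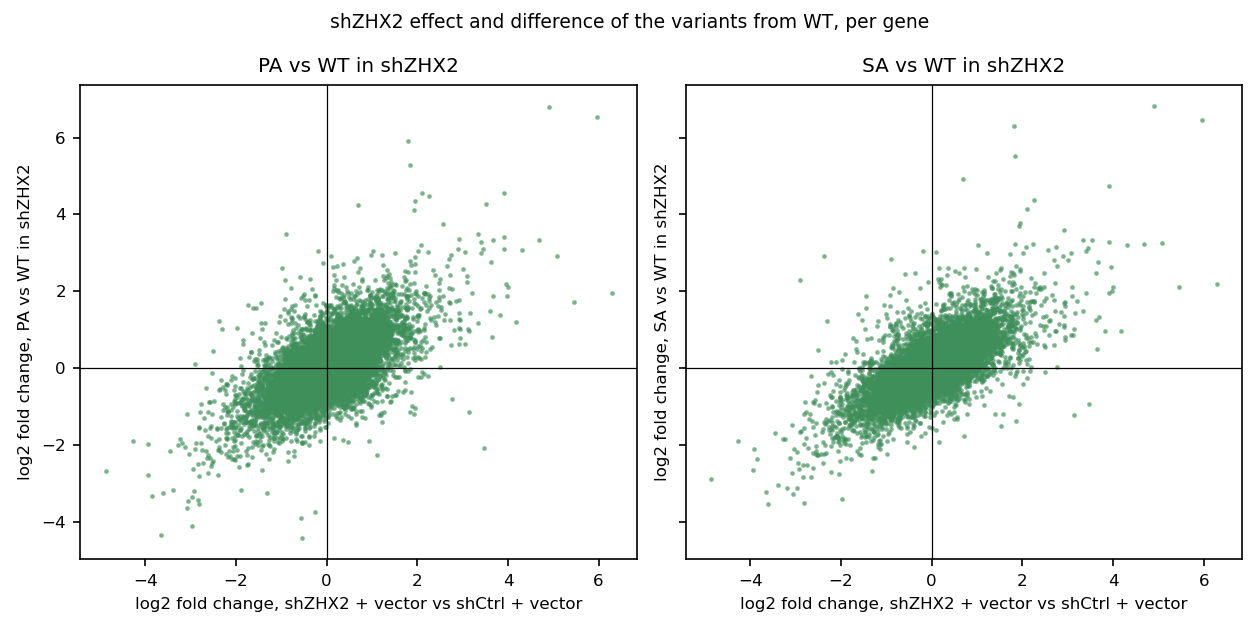
Log2 fold change of PA against WT (left) and SA against WT (right), vertical axes, against that of shZHX2 with vector over shCtrl with vector (horizontal axes) for each gene (point), n = 3 libraries per group. The 2 axes share no library, and the points rise together with correlations of 0.634 and 0.712.

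In sgZHX2 against sgCtrl, with ZHX2 at 0.13, LCAL1 rose 17.4-fold (6.75 ± 0.405 CPM against 0.384 ± 0.0994 CPM), CHAC1 9.65-fold (30.6 ± 2.79 CPM against 3.17 ± 0.234 CPM), KLHDC7B 9.40-fold, the detoxifying transferase GSTP1 6.54-fold (30.4 ± 0.705 CPM against 4.65 ± 0.0935 CPM) and SPRR3, of the cornified envelope, 5.995-fold. SLC40A1, the iron exporter ferroportin, fell from 155 counts to 1, a ratio of 156.3 with a counting interval of 27.6 to 6214. The chromatin organiser SATB1 fell 13.1-fold (0.118 ± 0.0680 CPM against 1.58 ± 0.351 CPM), ABCC11 8.10-fold, MATR3 5.56-fold, HOXA13 5.16-fold and the kinetochore motor CENPE 4.88-fold (3.13 ± 0.291 CPM against 15.3 ± 0.465 CPM). In teton_sgZHX2 against teton_control, LCAL1 (11.7-fold), CHAC1 (6.83-fold), GSTP1 (6.33-fold) and KLHDC7B (6.22-fold) rose, and SLC40A1 (241-fold, 0.0552 ± 0.0612 CPM against 14.6 ± 0.577 CPM), SATB1 (27.5-fold), ABCC11 (24.3-fold) and MGP, an inhibitor of calcification (13.1-fold, 3.88 ± 0.317 CPM against 50.7 ± 0.725 CPM), fell. Several of these falls were of genes abundant in the shRNA and hexanediol tables and near 0 in the rescue table. Of 106 such genes 57 were tested, and they made 9 of the 10 largest falls in the first comparison and 10 of 10 in the second; their median was 0.176 CPM in sgCtrl and 0.553 CPM in teton_control against 0.0375 and 0.0481 CPM in the sgZHX2 groups.

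Across all genes, sgZHX2 gave 5835 higher and 5699 lower (1263 and 961 at least 2-fold) and teton_sgZHX2 5434 and 5470 (815 and 665). Without the 106 genes the counts were 5826 and 5671, and 5428 and 5426. The comparisons shared 4903 higher genes (2009 expected) and 4833 lower genes (1975 expected), with 33 and 38 called in opposite directions, and their fold changes correlated with 0.874 across genes. Hypoxia response genes fell in 22 and rose in 6 of 29 cases with sgZHX2 and in 23 and 6 with teton_sgZHX2 (adjusted p = 0.000362 and 0.000157 with an estimated correlation), with LOX at -1.88 and -1.62. Cell cycle genes fell in 23 and 20 of 28 (adjusted p = 0.00286 and 0.00376), with TOP2A at -2.11 and -1.88, and cholesterol synthesis genes in 15 and 15 of 20 (adjusted p = 0.00312 and 0.00351), with INSIG1 at -1.82 and -1.51. Stress response genes rose in 13 and 12 of 20 (adjusted p = 0.00489 and 0.00819). The counts adjusted over the list alone were the same in these lists. NF-kB targets were higher in 13 and 14 of 19 (14 and 14 adjusted over the list alone, adjusted p = 0.24 and 0.13), with the cytokine gene IL6 at 3.28 and 3.47. HIF1A was at -1.53 and -1.20. Of the basal, fibroblast and leukocyte markers, 4 and 4 of 9 were higher and 1 and 4 lower (adjusted p = 0.24 and 0.248; median -0.10 and mean 0.13 with teton_sgZHX2); the basal keratin KRT17 stood at 1672 ± 14.8 CPM against 698 ± 8.31 CPM and at 1376 ± 7.61 CPM against 605 ± 6.44 CPM. The mitochondrial share was 2.51% to 2.95% in the controls and 1.67% to 1.82% in the sgZHX2 groups, and fold changes followed GC content across genes (Spearman rho 0.563 and 0.467).

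The test of the difference, the teton_sgZHX2 effect less the sgZHX2 effect, called 1891 genes with a more positive and 1315 with a more negative effect in the teton comparison, 17 and 68 of them by at least 2-fold. The 4 largest positive differences were SCDP1, a pseudogene whose counts are uncertain (1.25, SE 0.24), LPCAT2, of phospholipid remodelling (0.82, SE 0.16), the ciliary gene CEP290 (0.77, SE 0.12) and HDHD2 (0.77, SE 0.26). The 4 largest negative ones were PTGER3, a prostaglandin receptor (-1.74, SE 0.31), ABCC11 (-1.58, SE 0.52), MGP (-1.58, SE 0.13) and the adhesion molecule NCAM2 (-1.48, SE 0.29). Cell cycle genes had a more positive effect in 15 of 28 cases (adjusted p = 0.00868 with an estimated correlation), interferon genes in 12 of 21 (adjusted p = 0.00796), cholesterol synthesis genes in 11 of 20, with 1 more negative (adjusted p = 0.013), and heat shock genes in 7 of 14 (adjusted p = 0.013). Stress response genes had a more negative effect in 7 and a more positive one in 1 of 20 (adjusted p = 0.013). Adjusted over the list alone, 16, 12, 11 and 7 were more positive and 9 more negative in the same order, with 3 cholesterol synthesis, 1 interferon and 1 heat shock gene more negative and 3 stress response genes more positive. For BUB1, of the mitotic checkpoint, the effects were -1.83 with sgZHX2 and -1.28 with teton_sgZHX2, so that its positive difference marks a smaller fall. Of the 1315 more negative genes, 15 were among the 106 genes described above, as were 14 of the 68 that differed at least 2-fold, 5 of the 10 largest, and PTGER3, ABCC11 and MGP. DESeq2 gave 592 in place of 1315. The GC and length correction left 1105 and 314, and leaving out the first teton_control library left 866 more negative genes. In the same order the share of positive differences was 72.6%, 77.9% and 67.4% in place of 59.0%.

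The ZHX2-dependent hypoxia list was followed in the other tables, whose libraries had no part in its choice. The fold changes it was chosen on followed GC content (Spearman rho 0.694 for hypoxia and -0.222 for shZHX2), and those of the comparisons with a call for it did so as well: -0.296 for 1% hexanediol, -0.314 for 1% against 0.5%, -0.482 and -0.541 for PA and SA against vector, 0.563 and 0.467 for sgZHX2 and teton_sgZHX2 and -0.489 for their difference. With 1% hexanediol, 1744 of 2741 tested members were lower and 316 higher (median -0.61, adjusted p = 0.0133 with an estimated correlation), and with 0.5% 944 were lower and 305 higher (median -0.21, adjusted p = 0.0924). At 1% against 0.5%, 1397 were lower and 379 higher (adjusted p = 0.0374). In the rescue table, shZHX2 with vector gave 1080 lower and 943 higher of 2637 (adjusted p = 0.542), whereas of the 326 tested members that changed 2-fold in both comparisons 174 were lower and 53 higher (adjusted p = 0.00202). The set tests of these 2-fold members were added after the data were seen. WT against vector gave 941 higher and 1127 lower (median -0.06, adjusted p = 0.645), and of the 2-fold members 123 were higher and 92 lower (median 0.11, adjusted p = 0.0917). Against vector, PA gave 1222 lower and 261 higher (adjusted p = 0.00674) and SA 1178 and 289 (adjusted p = 0.0133); against WT they gave 1246 lower and 794 higher (adjusted p = 0.0748), and 1095 and 832 (adjusted p = 0.215). With sgZHX2, 1731 members were higher and 454 lower of 2737 (median 0.33, adjusted p = 0.0133), and with teton_sgZHX2 1560 and 527 (median 0.22, adjusted p = 0.0133). The difference of these effects was more negative for 530 members and more positive for 93 (adjusted p = 0.0133). For the 2-fold members the tests gave an adjusted p of 0.444 and 0.413 for 0.5% and 1% hexanediol, 0.568 for 1% against 0.5%, 0.164 for PA and 0.0954 for SA against vector, 0.0204 and 0.00966 for PA and SA against WT, 0.104 and 0.146 for the sgRNA comparisons and 0.0558 for their difference. These tests held far fewer genes. With 1% hexanediol 181 of 345 were lower and 37 higher (median -0.72), and with 0.5% the median was -0.39. The medians were 0.29 with sgZHX2 and 0.17 with teton_sgZHX2.

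Of the 10 followed genes, KISS1R and PRTN3 were not tested outside the shRNA table. ANGPTL4 fell in the rescue table with shZHX2 (-1.33, SE 0.03), rose with WT (1.69, SE 0.03) and was lower with PA and SA than with WT (-1.67 and -1.56); it fell with sgZHX2 (-0.72), with teton_sgZHX2 (-0.88) and with 1% hexanediol (-4.85). ISM2 fell with shZHX2 (-2.51, SE 0.09), rose with WT (2.01) and fell in both sgRNA comparisons (-1.07 and -1.21), while with 1% hexanediol its change of 0.08 had an adjusted p of 0.916. CCN5 fell with shZHX2 (-1.40, SE 0.03), rose with WT (1.19), fell in both sgRNA comparisons (-0.52 and -0.53) and fell with 1% hexanediol (-2.29, adjusted p = 0.044). PTPRN fell with shZHX2 (-1.16) and rose with WT (0.66). With sgZHX2 it had -0.01 (adjusted p = 0.892), and it fell with teton_sgZHX2 (-0.33, adjusted p = 9.97e-05). DPYSL4 fell with shZHX2 (-1.49), rose with WT (0.43) and fell in both sgRNA comparisons (-0.20 and -0.35). SLC16A3 fell with shZHX2 (-0.34) and with WT (-0.15; 0.31 after the GC and length correction) and rose in both sgRNA comparisons (0.97 and 0.73). ALDOC fell with shZHX2 (-0.17), with WT (-0.07, adjusted p = 0.0222; 0.11 after the GC and length correction) and in both sgRNA comparisons (-0.31 and -0.33). SPAG4 fell with shZHX2 (-0.31), rose with WT (0.37) and with sgZHX2 (0.33; -0.19 after the GC and length correction), and with teton_sgZHX2 had 0.08 (adjusted p = 0.13). With 1% hexanediol PTPRN (-0.89), SLC16A3 (-2.24) and SPAG4 (-2.15) fell. DPYSL4 and ALDOC had 0.51 and -1.52 there (adjusted p = 0.156 and 0.135).

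Across tables, fold changes were compared over genes tested in both. The shZHX2 effects of the shRNA and rescue tables correlated with 0.286, with 2017 genes higher in both (1596 expected) and 2094 lower in both (1608 expected). The shRNA table's shZHX2 effect correlated with -0.122 and -0.104 with the sgZHX2 and teton_sgZHX2 effects, whereas the rescue table's correlated with 0.497 and 0.477. The shRNA table's shZHX2 effect correlated with 0.321 and 0.305 with 0.5% and 1% hexanediol; the rescue table's did so with 0.113 and 0.097. These are 9 of the 18 correlations computed, all across genes, which are not independent replicates, and no p is given for them. Levels of marker genes set the tables apart: TFF1, an oestrogen-induced secreted protein, stood at 2.28 ± 0.268 CPM in shCtrl hypoxia and 4447 ± 105 CPM in shCtrl with vector, and KRT17 at 1.75 ± 0.155 CPM and 1187 ± 7.50 CPM, in tables that were not normalised together.

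**Figure D5:**
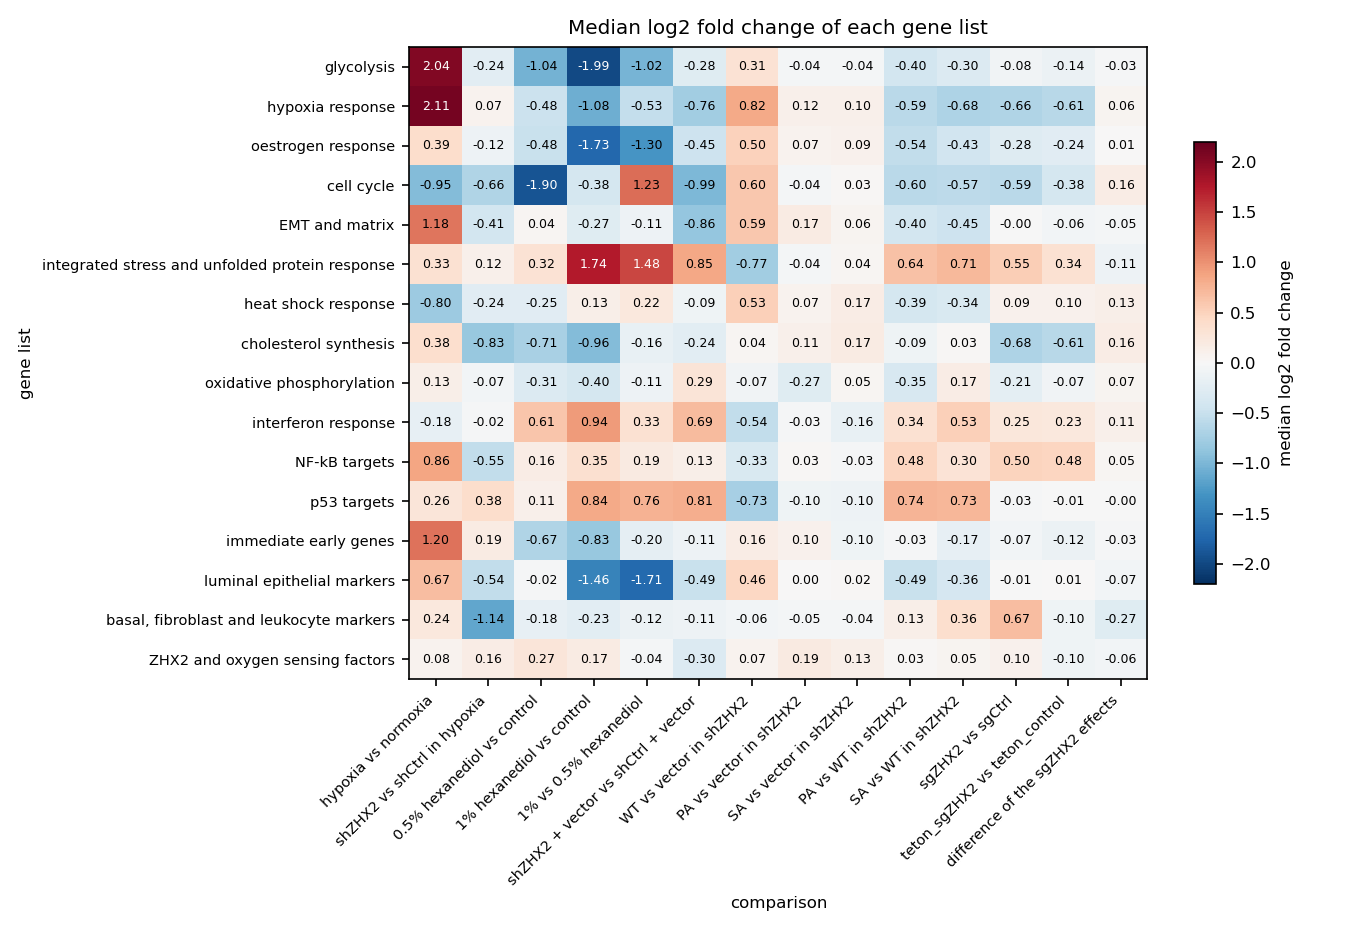
Median log2 fold change (colour and printed value) of the tested members of each of the 16 gene lists (vertical axis) in the 14 comparisons (horizontal axis), n = 3 libraries per group. Hypoxia response genes have a median of 2.11 in hypoxia and -0.76 with shZHX2 in the rescue table, and cell cycle genes one of -1.90 with 0.5% hexanediol.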

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

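The tests in this part were chosen after the results were seen, except the test of the difference of the sgZHX2 effects and those of GC bias and of length bias on the fold changes of hypoxia; for GC bias on the rise of glycolysis and hypoxia genes and for loss of transcripts with sgZHX2 editing the bounds were set before the values were seen, but the GC and length correction and the set of 106 genes they rest on were chosen after the data were seen.

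Results were looked at again where the sgZHX2 effect differed between the plain and the teton comparison in a test of the difference itself. It was more positive in the teton comparison for 1891 genes and more negative for 1315. The log2 differences were 1.25 for SCDP1, 0.82 for LPCAT2, 0.77 for CEP290, 0.77 for HDHD2, -1.74 for PTGER3, -1.58 for ABCC11, -1.58 for MGP and -1.48 for NCAM2. Of 100 splits of the 12 libraries, 2 gave as many genes as the real 3206, the real one included, and the highest other gave 3280. The 10 splits that kept the sgZHX2 libraries in place and exchanged control libraries gave 2037 to 3280 genes, and the 89 that exchanged sgZHX2 libraries gave 0 to 14. The share is under 0.05, but it rests on the splits that exchanged sgZHX2 libraries. With control libraries exchanged, the contrast still set the teton_sgZHX2 libraries against the sgZHX2 libraries. The number of genes thus follows mainly the difference between those libraries, whatever the grouping of the controls. It does not show that the effects against the controls differ, and a grouping of the control libraries by chance was not excluded. The control libraries also differ in a set of 106 genes abundant in the shRNA and hexanediol tables, which held PTGER3, ABCC11 and MGP, 14 of the 68 genes with a 2-fold more negative effect and 5 of the 10 largest.

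This set of 106 genes had a median of 12.8 to 23.7 CPM in the groups of the shRNA and hexanediol tables, 0.0138 to 0.019 CPM in the rescue table, and 0.176 CPM in sgCtrl, 0.553 CPM in teton_control and 0.0375 and 0.0481 CPM in the sgZHX2 groups; the tables were not normalised together. For the sgRNA table, counting or annotation that differs between tables is argued against by the 0.553 CPM in teton_control, within a table counted together. That value does not cover the rescue table, where this explanation was not tested. For MCF-7 cells in the rescue and sgRNA tables, 4 of 12 genes of 17q23 and 20q13 were higher by 1.5 times, fewer than the 7 set before the count; an exact interval of 9.92% to 65.1%, added after that count was seen, includes 7 of 12, and 8.81% of all 16217 genes were higher (Fisher's exact p = 0.0167, two-sided), so this stays open. For loss of these transcripts with sgZHX2 editing, their median with shZHX2 was -0.58 (bootstrap interval -0.63 to -0.34), above the bound of -1. Yet 71 of the 106 were called lower and 20 higher there, while of all 14903 genes tested 4955 were lower and 5006 higher. The set was chosen partly for at least 5 CPM in the shCtrl hypoxia libraries, the control of this comparison, and the other genes were not. That choice favours falls, so these counts do not show that the set fell more than other genes. The set did fall, and a knockdown is not an edit, so the bound cannot decide this. Cells or reads of another T47D library in the controls may account for the levels in the controls. Over the 60 genes at 20 CPM or more, a restriction not set beforehand, the percent of the hexanediol control level in teton_control had a quartile ratio of 2.83, under the bound of 4.

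The fold changes of hypoxia followed GC content (Spearman rho 0.694 over the 99.4% of genes with a value) and length (-0.316). A GC bias of the libraries alone is argued against by a median that was 1.18 higher (bootstrap interval 1.09 to 1.28) in short than in long AT-rich genes, and a length bias alone by long GC-rich genes lying 0.085 (0.03 to 0.137) above short ones. After the GC and length correction, 45 of 45 glycolysis and hypoxia response genes called higher remained so, with a median of 2.29 against 2.21, which argues against GC bias as the cause of their rise. The GC slope differed by 0.91 per 10 points of GC between hypoxia and normoxia, but with 1 set of libraries per condition the hypoxia treatment cannot be told apart from a joint effect of GC and length in library preparation.

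The second 0.5% hexanediol library was the lowest of its group in 45 of 49 glycolysis and hypoxia response genes, and the second 1% library in 46. For the 0.5% library, mislabelling is argued against by its correlation of 0.523 with the other 0.5% libraries, against 0.011 with the control and -0.271 with the 1% libraries. Library depth is argued against by its total of 14.8 (in units of 1e6 counts), within the range of the other 8 libraries. A weaker hypoxia exposure may account for the pattern in the 0.5% library. Its deviation from the other 0.5% libraries was taken for the 200 genes with the largest hypoxia falls in the shRNA table. Their median lay 0.16 above that of all genes (bootstrap interval 0.12 to 0.22), above the bound of 0.1. In the second 1% library, set against the other 1% libraries, the value was -0.01 (-0.04 to 0.02), under that bound. For the 200 genes with the largest hypoxia rises the values were -0.929 in the second 0.5% library and -0.445 in the second 1% library. No biological explanation was tested, since the labels give these libraries no condition of their own.

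For each comparison of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05, and 1 of them, the real one, gave as many genes. In these refits of the compared groups the real split gave 11461 genes for hypoxia, 9802 for shZHX2 in hypoxia, 6216 and 11085 for 0.5% and 1% hexanediol, 9691 for shZHX2 with vector, 9726, 6702 and 5870 for WT, PA and SA against vector, 9414 for PA against WT, 11340 for sgZHX2 and 10751 for teton_sgZHX2, and the highest other split gave 0 in each. For SA against WT the real split gave 9046 and the highest other 1. For 1% against 0.5% hexanediol, where the numbers were taken to pair the libraries, the real split gave 8668 and the other 3 of the 4 splits that part all pairs gave 0. For the genes higher in hypoxia and lower with shZHX2, 3 of 100 splits, the real one included, gave at least 2916, a share under 0.05. The highest other gave 3701, in a split that put the normoxia libraries in the place of the shCtrl hypoxia group. Its other groups mixed the shCtrl and shZHX2 libraries in hypoxia, so it counted genes higher in normoxia than in hypoxia. That count therefore cannot decide whether the hypoxic libraries were grouped by chance.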

How the results depend on the processing

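Scaling by library size only, the GC and length correction, leaving out both second hexanediol libraries or the 106 genes near 0 in the rescue table, and the set tests of 2-fold members were chosen after the results were seen. Of the 29 counts of genes, all 29 stayed within 1.5 times under RLE scaling, without the low-count filter, with only the groups compared and with the replicate block. Set tests and correlations were not run with library size only or the GC and length correction. Library size only gave 3385 higher genes in hypoxia, 5804 higher and 1794 lower with PA against vector, 2913 lower for PA against WT and 1199 hypoxia-induced genes lower with shZHX2; with the main scaling and a 2-fold limit in both comparisons this class held 451. The GC and length correction gave 2157 higher with PA, 1894 higher and 1894 lower with SA, and 1105 and 314 for the difference of the sgZHX2 effects, where DESeq2 gave 592 lower and leaving out 1 library gave 866 (without the first teton_control library) to 1435 lower (without the third). The causes were not tested. For the ZHX2-dependent list, a preset correlation gave an adjusted p of 1.64e-05 with 0.5% hexanediol, 0.00145 for PA and 0.0421 for SA against WT, and fry, which asks for a move against no change and not against other genes, 0.000348 with 0.5% hexanediol, 0.00026 with shZHX2 and vector, 0.0293 for WT against vector, and 2.1e-08 and 2.31e-06 for PA and SA against WT. Its 2-fold members gave 0.413 with 1% hexanediol, 0.568 for 1% against 0.5%, 0.00202 with shZHX2 and vector, 0.164 and 0.0954 for PA and SA against vector, 0.0204 and 0.00966 against WT, 0.104 and 0.146 for sgZHX2 and teton_sgZHX2 and 0.0558 for the difference. Of 224 fixed-list tests, 34 passed the threshold with the preset correlation and not with an estimated one, and 119 did so with fry. Of 919 named gene fold changes, 22 lost their call without the filter, 24 with DESeq2, 6 with the replicate block, 14 with library size only and 55 with the GC and length correction, and leaving out each library gave 188 lost and 13 gained calls in 5862 fits of them. The block gave 10 lower glycolysis genes at 0.5% hexanediol against 6. With library size only 5 called named fold changes changed sign: BIRC5 in hypoxia (-0.14), ALDOC with shZHX2 in hypoxia (0.011) and for PA against WT (0.11), KRT17 for PA against vector (0.05) and DDX58 for PA against WT (0.004). With the GC and length correction 22 did: in hypoxia PLOD2 (0.57), DUSP6 (0.048) and AGR2 (0.02), with shZHX2 CHORDC1 (-0.048), with 1% hexanediol 1 gene (-0.007), for WT against vector SLC16A3 (0.31), E2F1 (0.016) and ALDOC (0.11), for PA against vector NDUFS1 (-0.105), RELB (0.009) and KRT17 (0.12), for SA against vector KRT17 (0.053), SLC16A3 (0.092) and ALDOC (0.021), for PA against WT MKI67 (-0.088), with sgZHX2 CYC1 (-0.095), KRT7 (-0.096), SPAG4 (-0.19) and ZHX2 (-0.03), with teton_sgZHX2 CYC1 (-0.057) and KRT7 (-0.098), and DHCR7 for the difference of these effects (0.035). Over all genes, those called in both fits with opposite sign numbered 1035 in hypoxia, 185 with shZHX2 and 234 for PA against WT with library size only, and 2205 in hypoxia, 997 with sgZHX2, 571 with teton_sgZHX2 and 309 for WT against vector with the correction. Over genes with a log2 CPM of at least 3, all 18 correlations kept their sign. Each changed by at least the SD of its values with single libraries left out. For shZHX2 with vector, the change was from -0.782 to -0.794 with WT against vector, and from 0.477 to 0.582 with teton_sgZHX2. Outside the hexanediol doses the replicate numbers were not taken to pair the libraries. Depth and spread limit the weaker changes most for 1% against 0.5% hexanediol and for 0.5% against control, where 68.2% and 68.8% of simulated 2-fold changes were recovered.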

Other observations

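The levels in this part were looked at only after the results were seen, and no test between tables was run on them; they are means ± SD over n = 3 libraries in tables that were not normalised together.

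PGR, the progesterone receptor, stood at 269 ± 12.97 CPM in shCtrl normoxia, 72.4 ± 2.36 CPM in shCtrl hypoxia and 497.5 ± 21.1 CPM in the hexanediol control, but at 15.0 ± 0.948 CPM in shCtrl cells with vector and 17.7 ± 1.24 CPM in sgCtrl. TFF1 ran the other way, at 2.70 ± 0.0854 CPM in the hexanediol control and 2501 ± 50.7 CPM in sgCtrl. KRT17 was at 0.606 ± 0.0614 CPM in the hexanediol control and 698 ± 8.31 CPM in sgCtrl, and in the rescue table at 2000 ± 25.01 CPM with shZHX2 and vector, 1263 ± 2.83 CPM with WT, 1868 ± 40.4 CPM with PA and 1882 ± 28.8 CPM with SA. GATA3, a luminal transcription factor, stood between 129 and 336 CPM in the rescue groups and between 212 and 224 CPM in the sgRNA groups.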
